A study of Mus musculus with 12 samples.

How the data were processed

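RNA was sequenced from spleen and duodenum of mice given AC H6 or isotype antibody, with 3 libraries in each of 4 groups. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns, and total RNA went into an Illumina TruSeq RNA kit that does not mark strand. That protocol speaks of brain, while the tissue labels name spleen and duodenum, so a list of brain genes was among those tested. Per the submitters' processing notes, bcl2fastq 2.19, Trimmomatic, STAR 2.3 and edgeR were used with the mouse build mm10. The counting tool and its gene annotation are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene for each library, with 23329 rows, of which 2989 were 0 in all libraries. Per the file headers, the counts keep reads with several matches. In 58 pairs of genes the counts agreed within 1% (91 genes, among them the haemoglobin, Ccl21, amylase 2 and several defensin and MHC class I genes), so values of close paralogs are uncertain. Reads of overlapping genes on opposite strands cannot be told apart either.

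Groups came from the treatment and tissue labels and replicate numbers from the sample titles. The labels do not say that these numbers pair libraries or that spleen and duodenum came from the same mice. Gene positions are those of GENCODE M21 on GRCm38 (mm10), to which 22830 rows (97.9%) were matched by symbol or older symbol. Positions are given from the first to the last base of the gene, counted from 1, and the counts sum over its exons.

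From the deposited counts, edgeR 4.0.16 in R 4.3.3 gave trimmed mean of M values (TMM) scaling factors, CPM, and the quasi-likelihood F-test (glmQLFit, glmQLFTest) after filtering with filterByExpr. Each tissue was fitted on its own 6 libraries without covariates. The interaction of tissue and treatment was fitted on all 12. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the square root of the F statistic, a quotient that becomes unstable for changes near 0. A fitted log2 fold change of a gene with few counts depends on a prior count, and where a group held 1 to 3 counts the ratio of CPM is given with its 95% exact counting interval, which covers counting error only. A gene at 0 in a group is set against a floor of 3 counts over the group.

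The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The 41 lists hold 555 entries, of which 550 were found, 8 of them by another name of the gene. Igha, Ly6g, Ahsp, Muc2 and Sh2d6 had no row of that name and were not analysed here. Clca1 is carried by the row Clca3 through a change of symbols, a match corrected after values had been seen. The lists cover the LTbR pathway, lymphoid stroma chemokines, NF-kB, type I and II interferon, MHC classes I and II, antimicrobial genes, interleukins 17 and 22, IgA switching and complement. Others hold cell cycle, germinal centre, clock, immediate early genes, cholesterol synthesis, lipid absorption, iron, and drug metabolism. The rest mark blood and immune cell types, stroma, endothelium, the epithelial cell types of the intestine, pancreatic acinar cells and brain. They were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01, adjusted over the lists with at least 3 tested members. Camera with an estimated correlation was the alternative.

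Named genes were, per tissue, the 12 largest rises and 8 largest falls among called genes with complete separation of the groups and a mean log2 CPM of at least 1, leaving out predicted models and immunoglobulin or T cell receptor segments. To these came the LTbR pathway list, Cxcl13, Ccl19, Ccl21a, Madcam1, Icam1 and Vcam1 whatever their p, up to 4 members of smallest p from each described list, and the 10 interaction genes of smallest adjusted p. Genes named outside the rule are said to be so.

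Alternatives were DESeq2-style size factors, no filter on low counts, a stricter filter (10 counts in every library of a group and mean log2 CPM of 1), DESeq2 1.42.0, limma-voom, 1 fit of all 12 libraries, the replicate number as a block, and each library left out in turn. After the data were seen, fits without haemoglobin, Rn45s, Lars2 and amylase 2 genes, with an erythroid score and with an acinar score were added. Other splits of the 6 libraries of a tissue were refitted, 10 per tissue, and 100 were drawn for the interaction. No 2 libraries were identical. The chi-square per degree of freedom between libraries of a group ran from 25.9 to 255, so none was a repeat of another within sampling noise.

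Each test was tested on simulated data drawn from the real means and depths with 200 genes changed. In the simulated spleen comparison of 15270 genes, edgeR recovered 31 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 10 of its 164 calls (6.10%) were unchanged genes. In the simulated duodenum comparison of 15667 genes it recovered 36 of 67, 59 of 67 and 64 of 66, and 24 of 183 calls (13.1%) were unchanged genes. In the simulated interaction of 16655 genes it recovered 6 of 67, 47 of 67 and 52 of 66, and 4 of 109 calls (3.67%) were unchanged genes. The share of unchanged genes among DESeq2 calls was 13.6%, 21.9% and 15.1% in these 3 simulations. The edgeR shares for spleen and duodenum also lay above the threshold of 0.05. With 200 genes changed, against 5428 called in the real duodenum, these shares and recoveries do not carry over to that comparison. Camera called the changed list in each and 0 unchanged lists. The simulated genes were drawn independently of each other, so this does not show how camera fares with correlated genes. In the real spleen libraries the estimated correlation was 0.97 for the cell cycle list and 0.96 for the erythroid list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.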

Results

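Messenger RNA was measured in the spleen and the duodenum of wild type mice of C57BL/6J, a common inbred laboratory strain, aged 2 months. The mice had received either AC H6, an agonist antibody to the lymphotoxin beta receptor (LTbR), or an isotype control, which is an antibody of the same class without that target. LTbR is a receptor of the tumour necrosis factor receptor family that signals through the alternative NF-kB pathway and is needed for lymph node and Peyer's patch formation. Each mouse was given 100 ul of a 1 mg/ml solution and the tissues were taken 24 hours later. There were 3 libraries in each of 4 groups, 12 in all. Total counts per library ran from 13874091 in spleen isotype replicate 1 to 45847467 in spleen AC H6 replicate 1. Values below are means ± SD in CPM (counts scaled to a common library size), n = 3 libraries per group, and log2 fold changes of AC H6 over isotype ± standard error. The design text names 3 mice per treatment and speaks of a dose per mouse. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these samples.

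Some transcripts took unequal shares of the libraries. Haemoglobin genes held 12.1%, 19.0% and 7.59% of the counts in the spleen isotype libraries 1, 2 and 3, and 28.3%, 15.7% and 22.5% in the AC H6 libraries 1, 2 and 3. The ribosomal precursor Rn45s held 7.56% of duodenum isotype 1 and 1.18% of duodenum AC H6 2, against 0.206% or less in the other 4 duodenum libraries. The amylase 2 genes of the exocrine pancreas, which lies against the duodenum, held 2.11% of duodenum isotype 2, 0.737% of AC H6 2 and 8.55% of AC H6 3. They held 0.0261% or less of the other 3 duodenum libraries.

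The first comparison asked which spleen transcripts differ 24 hours after LTbR was engaged. The clearest rise was in genes of neutrophils, the granule-filled phagocytes: of the neutrophil list 12 rose and 1 was not called of 13 measured (13 higher when adjusted over the list alone). Its median was 1.48 (camera adjusted p = 1.13e-11, and adjusted p = 0.447 with an estimated correlation). S100a9, a subunit of the antimicrobial protein calprotectin (chromosome 3, 90692632 to 90695721, minus strand), went from 221 ± 47.4 to 651 ± 126 CPM, a log2 change of 1.56 ± 0.19 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0157). Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 1.09 ± 0.09, the collagenase gene Mmp8 by 1.16 ± 0.09 and the gelatinase gene Mmp9 by 0.96 ± 0.11. Among the 12 largest rises named by rule were more myeloid genes, of which Lcn2 also stands in the neutrophil list. Mpo, myeloperoxidase (chromosome 11, 87793581 to 87804413, plus strand), went from 51.1 ± 18.2 to 149 ± 26.2 CPM. Prtn3, the granule protease proteinase 3, rose by 1.79 ± 0.30 and Lcn2, the iron-siderophore binding lipocalin 2, by 1.62 ± 0.26. Hp, haptoglobin (chromosome 8, 109575128 to 109579172, minus strand), went from 17.1 ± 2.99 to 54.5 ± 8.01 CPM (log2 1.68 ± 0.15), and Hdc, which makes histamine (chromosome 2, 126593667 to 126619299, minus strand), from 6.74 ± 0.0743 to 20.2 ± 1.02 CPM (log2 1.58 ± 0.07, edgeR adjusted p = 8.13e-04, the smallest of this comparison). Slfn4, a Schlafen family gene whose reads can be shared with its paralogs (chromosome 11, 83175186 to 83190216, plus strand), had the largest named log2 change, 2.12 ± 0.20.

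The rest of the named rises in spleen were Mrgpra2b at 2.04 ± 0.27, whose reads can also fall on the related Mrgpra2a, Il1f9 (interleukin 36 gamma) at 1.99 ± 0.26, Abca13 at 1.79 ± 0.28, Ms4a3 at 1.61 ± 0.18 and Trem3 at 1.56 ± 0.22. Some genes stimulated by type I interferon rose as well: 6 rose and 16 were not called of 22 measured (15 higher when adjusted over the list alone). Their median was 0.58 (camera adjusted p = 1.97e-06, and adjusted p = 0.492 with an estimated correlation). Oas1a, a sensor of double-stranded RNA, went from 24 ± 2.33 to 44.7 ± 4.86 CPM, and Oasl2, Oas2 and Ifit1 rose by 0.79 ± 0.12, 0.77 ± 0.16 and 0.71 ± 0.13. Of the complement genes 7 rose and 9 were not called of 16 measured (7 higher when adjusted over the list alone). Their median was 0.18 (camera adjusted p = 2.40e-04, and adjusted p = 0.492 with an estimated correlation). C5ar1, the C5a receptor of myeloid cells, rose by 1.38 ± 0.09 and the 3 chains of C1q by 0.45 ± 0.07 (C1qa), 0.55 ± 0.08 (C1qb) and 0.54 ± 0.08 (C1qc). In the antimicrobial and acute phase list 4 rose and 6 were not called of 10 measured (4 higher when adjusted over the list alone). Its median was 0.42 (camera adjusted p = 0.0132, and adjusted p = 0.447 with an estimated correlation), and 3 of its members, Lcn2, S100a8 (1.52 ± 0.19) and S100a9, are also in the neutrophil list. Nos2, inducible nitric oxide synthase, lay at 0.81 ± 0.12.

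Some macrophage and monocyte markers rose in spleen. Of the marginal zone macrophage list 4 rose and 2 were not called of 6 measured (4 higher when adjusted over the list alone). Its median was 0.61 (camera adjusted p = 8.64e-04, and adjusted p = 0.447 with an estimated correlation). The scavenger receptor gene Marco (chromosome 1, 120474538 to 120505024, minus strand) went from 94.6 ± 1.42 to 209 ± 33.9 CPM, and Cd209b, the lectin SIGN-R1 of these cells, from 9.86 ± 1.2 to 25.2 ± 7.61 CPM. Nr1h3, the liver X receptor alpha, rose by 0.46 ± 0.06 and Msr1 by 0.76 ± 0.14. Of the monocyte genes 3 rose and 5 were not called of 8 measured (4 higher when adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.0438, and adjusted p = 0.492 with an estimated correlation). F13a1 lay at 1.22 ± 0.13, Ly6c2 at 0.46 ± 0.06 and Chi3l3 at 1.48 ± 0.24. The monocyte call had an adjusted p of 0.0536 without isotype 2, 0.0921 without AC H6 2 and 0.0584 without AC H6 3. Of the red pulp macrophage list 2 rose, 1 fell and 7 were not called of 10 measured (4 higher and 1 lower when adjusted over the list alone). Its median was 0.13 (camera adjusted p = 0.0885). Csf1r, the receptor of macrophage colony-stimulating factor, rose by 0.37 ± 0.07 and Cd5l by 0.33 ± 0.07, while Hmox1, heme oxygenase 1, fell from 416 ± 15.4 to 288 ± 20.7 CPM.

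Genes of dividing cells, red cell precursors and platelets lay higher as lists in spleen, with haemoglobin shares that varied widely within each group. For the cell cycle list edgeR called 0 of 20 (9 higher when adjusted over the list alone). DESeq2 called 4 of them, limma-voom 0, and 18 had an unadjusted p under 0.05. The list as a whole had a median of 0.85 (camera adjusted p = 3.00e-06, and adjusted p = 0.633 with an estimated correlation). Top2a, topoisomerase II alpha, had a log2 change of 0.86 ± 0.26 (edgeR adjusted p = 0.0981). For the erythroid list edgeR called 0 of 15 (0 called when adjusted over the list alone). With 6 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 0. Its median was 1.17 (camera adjusted p = 2.40e-04, and adjusted p = 0.652 with an estimated correlation). Alas2, the first enzyme of haem synthesis in red cells, went from 587 ± 283 to 1313 ± 475 CPM (edgeR adjusted p = 0.12), and Hbb-b1 and Hbb-b2, whose counts are nearly the same, had a log2 change of 1.08 ± 0.41. Of the megakaryocyte and platelet genes 3 rose and 5 were not called of 8 measured (8 higher when adjusted over the list alone). Their median was 0.68 (camera adjusted p = 4.11e-05, and adjusted p = 0.492 with an estimated correlation). Pf4, platelet factor 4, lay at 0.89 ± 0.14, Itga2b at 0.65 ± 0.13 and Ppbp at 0.74 ± 0.16. With the mean log2 CPM of the erythroid list as a covariate, a setting added after the data were seen, 207 genes were called in place of 608, 12 of 13 neutrophil genes among them, and the neutrophil median was 1.01.

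Some T cell, B cell, MHC class II and dendritic cell genes fell slightly in spleen. Of the T cell genes 4 fell and 8 were not called of 12 measured (11 lower when adjusted over the list alone). Their median was -0.34 (camera adjusted p = 2.02e-06, and adjusted p = 0.492 with an estimated correlation). Tcf7 went from 172 ± 9.33 to 125 ± 6.67 CPM, and Cd3e, a chain of the T cell receptor complex, Cd28 and Cd5 fell by 0.43, 0.47 and 0.35 on the log2 scale. Of the B cell genes 2 fell and 10 were not called of 12 measured (11 lower when adjusted over the list alone). Their median was -0.33 (camera adjusted p = 2.46e-06, and adjusted p = 0.492 with an estimated correlation). Fcrla lay at -0.40 ± 0.08. Of the MHC class II list 2 fell and 8 were not called of 10 measured (8 lower when adjusted over the list alone). Its median was -0.26 (camera adjusted p = 4.39e-05, and adjusted p = 0.492 with an estimated correlation). H2-Ob lay at -0.39 ± 0.07 and H2-Oa at -0.29 ± 0.06. Of the dendritic cell genes 2 fell and 11 were not called of 13 measured (4 lower when adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.136). Cd209a, the lectin DC-SIGN (chromosome 8, 3743397 to 3748984, minus strand), fell from 16.4 ± 2.59 to 8.05 ± 0.919 CPM and Ccr7, the receptor for Ccl19 and Ccl21, by 0.36 on the log2 scale. In the natural killer and cytotoxic list 1 rose, 1 fell and 9 were not called of 11 measured (1 higher and 2 lower when adjusted over the list alone). Its median was -0.07 (camera adjusted p = 0.543). Klrd1 lay at -0.58 ± 0.07 and Gzmb, granzyme B, at 0.67 ± 0.10.

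The other 7 largest named falls in spleen were low or moderate in level. Stra6, the receptor for retinol-binding protein (chromosome 9, 58063788 to 58153996, plus strand), fell from 2.94 ± 0.97 to 1.09 ± 0.361 CPM (log2 -1.51 ± 0.32, edgeR adjusted p = 0.0462). Cyr61, a matrix-associated signalling protein (chromosome 3, 145646976 to 145649981, minus strand), fell from 24.6 ± 0.661 to 11.7 ± 1.88 CPM and Ubd, the ubiquitin-like modifier FAT10 (chromosome 17, 37193892 to 37196095, plus strand), from 6.09 ± 0.928 to 2.9 ± 0.708 CPM. Gal3st2, which can share reads with Gm9994, Csdc2 and Cacna1b, a neuronal calcium channel subunit, had log2 changes of -1.38 ± 0.12, -1.21 ± 0.18 and -1.11 ± 0.19. Tnnt3, fast skeletal troponin T, changed by -1.02 ± 0.16, while Acta1, the abundant actin of skeletal muscle looked up after its neighbours had been seen, had a value of -0.06 ± 0.18 (edgeR adjusted p = 0.899).

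Genes of the LTbR pathway itself did not pass the test in spleen: edgeR called 0 of 11 (0 called when adjusted over the list alone). Of these, 2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Their median was -0.03 (camera adjusted p = 0.952). The log2 changes were 0.21 ± 0.09 for the receptor gene Ltbr (chromosome 6, 125306571 to 125313885, minus strand), -0.18 ± 0.08 for Lta and -0.07 ± 0.08 for Ltb, which encode its ligand lymphotoxin, and 0.21 ± 0.10 for Tnfsf14, the ligand LIGHT. The signalling genes lay at 0.03 ± 0.08 (Traf2), -0.03 ± 0.09 (Traf3), 0.08 ± 0.07 (Birc2), -0.26 ± 0.07 (Map3k14, the NF-kB inducing kinase NIK) and -0.04 ± 0.05 (Chuk). The transcription factor genes Nfkb2 (chromosome 19, 46304320 to 46312385, plus strand) and Relb (chromosome 7, 19606217 to 19629438, minus strand) lay at 0.19 ± 0.09 and -0.14 ± 0.08. For the list of lymphoid stroma chemokines and adhesion molecules edgeR called 0 of 16 (0 called when adjusted over the list alone). DESeq2 called 1 of them, limma-voom 0, and 3 had an unadjusted p under 0.05. Its median was -0.04 (camera adjusted p = 0.757). Cxcl13, which draws B cells into follicles, went from 112 ± 17.1 to 103 ± 8.32 CPM, Ccl19 had a log2 change of 0.03 ± 0.06 and Ccl21a, which shares its reads with near-identical copies, -0.06 ± 0.13. Madcam1, Icam1 and Vcam1, adhesion molecules of vessels and stroma, lay at -0.29 ± 0.08, -0.01 ± 0.06 and 0.26 ± 0.07. Of the NF-kB target genes 1 rose and 20 were not called of 21 measured (1 higher when adjusted over the list alone). Their median was 0.00 (camera adjusted p = 0.757), the call being Il1b at 0.58 ± 0.12.

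Further spleen lists held a few calls. Dgat2, Scarb1 and Slc27a4 rose by 0.79 ± 0.08, 0.35 ± 0.06 and 0.29 ± 0.06 in the intestinal lipid absorption list, of which 3 rose and 10 were not called of 13 measured (3 higher when adjusted over the list alone). Its median was 0.29 (camera adjusted p = 8.64e-04, and adjusted p = 0.447 with an estimated correlation). These 3 genes serve triglyceride synthesis, lipoprotein uptake and fatty acid uptake in many cells, not in the gut alone. Among interferon gamma genes 1 rose, 1 fell and 17 were not called of 19 measured (1 higher and 1 lower when adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.757). The chemokine gene Cxcl10 lay at 0.76 ± 0.09 and Cxcl9 at -0.29 ± 0.06. Of the iron genes 2 fell and 8 were not called of 10 measured (1 higher and 2 lower when adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.57). Cybrd1 lay at -0.66 ± 0.10 beside Hmox1. In the stroma list 1 rose and 11 were not called of 12 measured (1 higher and 3 lower when adjusted over the list alone). Its median was -0.25 (camera adjusted p = 0.0885), the rise being desmin, Des, at 0.58 ± 0.06. Of the endothelium list 1 rose and 9 were not called of 10 measured (2 higher when adjusted over the list alone), with Plvap at 0.39 ± 0.07 and a median of -0.02 beside a mean of 0.03 (camera adjusted p = 0.952). Of the tuft cell genes 2 rose and 5 were not called of 7 measured (2 higher when adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.373). Alox5ap, which leukocytes also express, rose by 0.38 ± 0.06. Of the drug metabolism genes 1 rose and 10 were not called of 11 measured (1 higher when adjusted over the list alone) (camera adjusted p = 0.147). Ugt1a1 lay at 0.63 ± 0.10. Of the IgA switch list 1 fell and 9 were not called of 10 measured (2 lower when adjusted over the list alone) (camera adjusted p = 0.854). Tnfrsf13b lay at -0.34 ± 0.07. Of the clock genes 1 fell and 15 were not called of 16 measured (1 lower when adjusted over the list alone) (camera adjusted p = 0.27). Cry2 lay at -0.37 ± 0.07.

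The other 14 spleen lists had no called member by edgeR and no call as a list. For MHC class I edgeR called 0 of 15 (0 called when adjusted over the list alone). With 4 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 1 (camera adjusted p = 0.476). B2m lay at 0.21 ± 0.06. For the interleukin 17 and 22 axis edgeR called 0 of 7 (1 lower when adjusted over the list alone). Of these, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (camera adjusted p = 0.112). Il17ra lay at -0.24 ± 0.06. In the germinal centre list edgeR called 0 of 9 (0 called when adjusted over the list alone). DESeq2 called 0 of them, limma-voom 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.952). In the immediate early and stress list edgeR called 0 of 16 (0 called when adjusted over the list alone). With 4 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 0 (camera adjusted p = 0.57). Among plasma cell genes edgeR called 0 of 9 (0 called when adjusted over the list alone). Of these, 2 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0 (camera adjusted p = 0.65). Xbp1 lay at 0.33 ± 0.10. Among cholesterol synthesis genes edgeR called 0 of 16 (0 called when adjusted over the list alone). DESeq2 called 0 of them, limma-voom 0, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.957). In the enterocyte list edgeR called 0 of 11 (0 called when adjusted over the list alone). With 0 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 0 (camera adjusted p = 0.373). For goblet cells edgeR called 0 of 6 (1 higher when adjusted over the list alone). Of these, 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (camera adjusted p = 0.12). For Paneth cells edgeR called 0 of 6 (0 called when adjusted over the list alone). DESeq2 called 0 of them, limma-voom 0, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.854). For intestinal stem cells edgeR called 0 of 9 (1 higher and 2 lower when adjusted over the list alone). With 3 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 1 (camera adjusted p = 0.495). For enteroendocrine cells edgeR called 0 of 4 (0 called when adjusted over the list alone). Of these, 0 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0 (camera adjusted p = 0.987). For M cells edgeR called 0 of 10 (2 higher and 2 lower when adjusted over the list alone). DESeq2 called 3 of them, limma-voom 0, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.65). Spib lay at -0.26 ± 0.08. For pancreatic acinar cells edgeR called 0 of 11 (0 called when adjusted over the list alone). With 0 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 0 (camera adjusted p = 0.65). Pnlip went from 7.71 ± 12.5 to 1.77 ± 2.24 CPM. For brain edgeR called 0 of 7 (0 called when adjusted over the list alone). Of these, 2 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0 (camera adjusted p = 0.108). Gad1 lay at -0.42 ± 0.12. Median and mean differed in sign, or from the direction of the test, in the germinal centre (0.01 and 0.01), cholesterol synthesis (-0.02 and 0.01), Paneth (-0.04 and 0.11), enteroendocrine (0.14 and -0.02) and endothelium lists.

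Of 15270 genes tested in spleen, edgeR called 315 higher and 293 lower with AC H6 at an adjusted p under 0.05, 608 in all or 3.98%. Of these 64 and 26 changed by more than 1 on the log2 scale. In all 608 every AC H6 library lay above or below every isotype library, as in 4970 of all genes tested, where chance alone gives 10%. The camera test called 13 of 41 lists, 10 up and 3 down, and 0 with an estimated correlation, with 4 lists at an unadjusted p under 0.05. The count of genes moved with each library left out: it was 14 without isotype 1, 68 without isotype 2, 104 without isotype 3, 76 without AC H6 1, 1132 without AC H6 2 and 30 without AC H6 3. Of the 71 called genes that the naming rule picked, 6 stayed past the threshold whichever library was left out (Hp, Hdc, Gal3st2, C5ar1, Mmp8 and Csf3r).

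**Figure D1:**
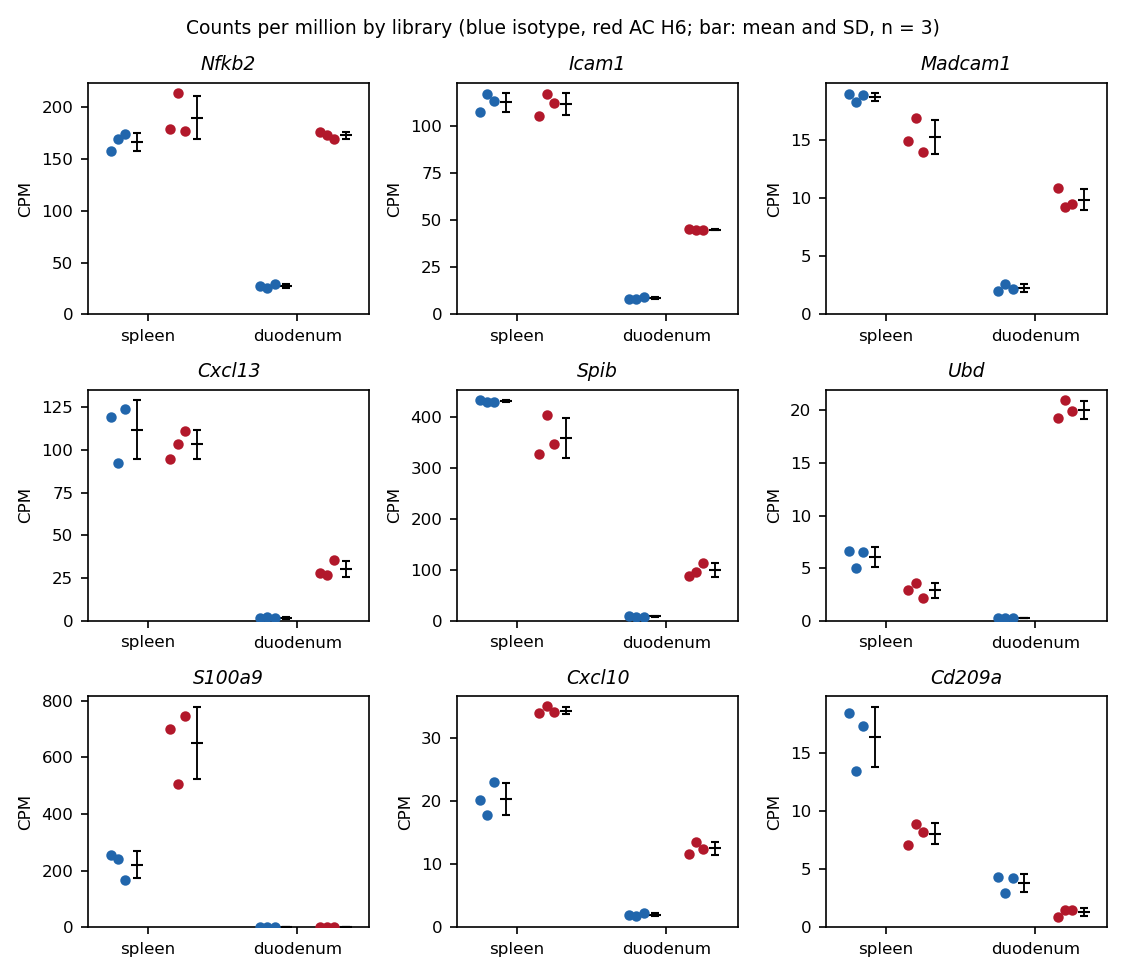
Normalised expression in CPM of 9 genes in each of the 12 libraries, 1 panel per gene, with the groups (isotype and AC H6, spleen and duodenum) along the horizontal axis, 1 point per library and a bar for the mean ± SD. Nfkb2, Icam1, Cxcl13 and Spib lie higher with AC H6 in duodenum, S100a9 and Cxcl10 lie higher in both tissues, and Cd209a lies lower in both.

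The duodenum comparison asked the same of that tissue, the first part of the small intestine, where most LTbR pathway genes rose. Of this list 7 rose, 1 fell and 2 were not called of 10 measured (7 higher and 2 lower when adjusted over the list alone). Its median was 0.97 (camera adjusted p = 0.00393, and adjusted p = 0.264 with an estimated correlation). Nfkb2, which encodes the p100/p52 subunit of the alternative pathway, went from 27.4 ± 2.01 to 173 ± 3.01 CPM, a log2 change of 2.66 ± 0.08 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.68e-07). Map3k14 (chromosome 11, 103219762 to 103267472, minus strand) rose by 1.59 ± 0.07, Relb by 1.06 ± 0.09, the adaptor genes Traf3 and Traf2 by 1.02 ± 0.08 and 0.93 ± 0.05, Ltb by 1.46 ± 0.15 and Birc2 by 0.21 ± 0.06. Chuk, the kinase IKK alpha, fell by 0.46 on the log2 scale. The receptor gene Ltbr went from 134 ± 3.32 to 119 ± 3.41 CPM, log2 -0.18 ± 0.06 (edgeR adjusted p = 0.0531, 0.0203 to 0.158 over the alternatives), and Tnfsf14 lay at -0.05 ± 0.28. Psd, on the opposite strand and overlapping Nfkb2 in exons, rose by 1.29 ± 0.09, and since the library kit did not mark strand the reads of these 2 genes cannot be told apart where they overlap.

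Most chemokines and adhesion molecules of lymphoid stroma rose in duodenum: 10 rose, 2 fell and 4 were not called of 16 measured (11 higher and 2 lower when adjusted over the list alone). Their median was 1.26 (camera adjusted p = 3.62e-06, and adjusted p = 0.178 with an estimated correlation). Cxcl13 (chromosome 5, 95956951 to 95961068, plus strand) went from 1.81 ± 0.399 to 30.2 ± 4.56 CPM (log2 4.03 ± 0.16, edgeR adjusted p = 3.22e-06). Ccl19, which has further gene copies that can share its reads (chromosome 4, 42754525 to 42756577, minus strand), rose by 3.32 ± 0.24 and Ccl21a (chromosome 4, 42772860 to 42773993, minus strand) by 1.21 ± 0.09. Madcam1 (chromosome 10, 79664559 to 79668537, plus strand), the vessel ligand of gut-homing lymphocytes, went from 2.26 ± 0.344 to 9.88 ± 0.899 CPM, Icam1 (chromosome 9, 21015985 to 21028817, plus strand) from 8.61 ± 0.563 to 44.8 ± 0.227 CPM and Vcam1 (chromosome 3, 116109949 to 116129688, minus strand) from 13.8 ± 0.574 to 31.9 ± 1.29 CPM. Mfge8, a secreted protein that bridges dying cells and phagocytes (chromosome 7, 79133768 to 79149060, minus strand), went from 75.7 ± 2.83 to 597 ± 15.7 CPM, a log2 change of 2.98 ± 0.06 (edgeR adjusted p = 8.73e-08). Among the NF-kB target genes 17 rose, 2 fell and 4 were not called of 23 measured (18 higher and 2 lower when adjusted over the list alone). Their median was 0.88 (camera adjusted p = 3.59e-06, and adjusted p = 0.178 with an estimated correlation). The inhibitor gene Nfkbie lay at 1.74 ± 0.10 and the ubiquitin ligase gene Birc3 at 0.88 ± 0.07. Nfkb2 and Relb stand in both this list and the pathway list.

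Markers of M cells, the epithelial cells over lymphoid follicles that take up antigen from the lumen, rose in duodenum: 11 rose of 11 measured (11 higher when adjusted over the list alone). Their median was 1.80 (camera adjusted p = 8.99e-09, and adjusted p = 0.191 with an estimated correlation). Spib, an Ets transcription factor that M cells need (chromosome 7, 44525993 to 44532071, minus strand), went from 8.71 ± 0.811 to 99.7 ± 13.2 CPM (log2 3.52 ± 0.11, edgeR adjusted p = 9.88e-07). The chemokine gene Ccl9 (chromosome 11, 83572919 to 83578636, minus strand) went from 13.4 ± 2.13 to 107 ± 7.09 CPM, Marcksl1 (chromosome 4, 129513581 to 129515985, plus strand) from 8.54 ± 0.171 to 54.7 ± 3.3 CPM and Anxa5 rose by 0.97 ± 0.06. Gp2, an M cell receptor that is also made in the pancreas, went from 14.3 ± 10.6 to 50.9 ± 31.5 CPM (log2 1.80 ± 0.54, edgeR adjusted p = 0.033), and in each group it was highest in the library richest in amylase 2 (isotype 2 and AC H6 3). For the pancreatic acinar list edgeR called 0 of 16 (0 called when adjusted over the list alone). DESeq2 called 0 of them, limma-voom 0, and 1 had an unadjusted p under 0.05. Its median was 1.97 (camera adjusted p = 0.507). Rnase1 went from 32.8 ± 26.9 to 118 ± 129 CPM. Of the B cell genes, abundant in follicles, 2 rose and 9 were not called of 11 measured (2 higher when adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.0183, and adjusted p = 0.248 with an estimated correlation). Cd22 lay at 0.73 ± 0.12 and Cd72 at 0.37 ± 0.09.

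Beyond Cxcl13, Spib, Ccl9 and Mfge8, the 12 largest named rises in duodenum were as follows. Ubd went from 0.291 ± 0.0238 to 20.1 ± 0.837 CPM (log2 6.10 ± 0.12, edgeR adjusted p = 8.73e-08). Stra6 had 3 counts over the isotype libraries and 458 over the AC H6 libraries, a CPM ratio of 117 (95% counting interval 39.7 to 569). Psg25, of a family with close paralogs (chromosome 7, 18519702 to 18532269, minus strand), went from 1.01 ± 0.196 to 34.7 ± 5.95 CPM, the adhesion receptor gene Gpr133 (chromosome 5, 129096750 to 129204599, plus strand) from 11.4 ± 2.35 to 136 ± 14 CPM, and Il4i1, a secreted amino acid oxidase (chromosome 7, 44816387 to 44840809, plus strand), from 1.48 ± 0.276 to 16.8 ± 0.549 CPM. Its exon neighbours on the opposite strand, Atf5 and Tbc1d17, lay at 0.01 ± 0.14 and 0.15 ± 0.07, and Nup62 on the same strand at 0.21 ± 0.07. The joint row Nup62-il4i1, named outside the rule, rose by 1.66. Ces3a, a carboxylesterase with close paralogs (chromosome 8, 105048601 to 105058413, plus strand), Fut1, a fucosyltransferase (chromosome 7, 45617289 to 45621059, plus strand), and Colq, the collagen tail of acetylcholinesterase (chromosome 14, 31523082 to 31591343, minus strand), rose by 3.25 ± 0.14, 3.05 ± 0.18 and 2.98 ± 0.19.

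Most interferon and antigen presentation genes rose in duodenum. Of the type I interferon list 19 rose and 3 were not called of 22 measured (20 higher when adjusted over the list alone). Its median was 1.08 (camera adjusted p = 6.08e-10, and adjusted p = 0.248 with an estimated correlation). Bst2 (tetherin) lay at 1.43 ± 0.07, Isg15 at 1.42 ± 0.10, Irf7 at 1.08 ± 0.08 and Oas1a at 1.27 ± 0.09. Of the interferon gamma genes 19 rose and 1 was not called of 20 measured (19 higher when adjusted over the list alone). Their median was 0.94 (camera adjusted p = 6.08e-10, and adjusted p = 0.248 with an estimated correlation). Cxcl10 went from 2 ± 0.249 to 12.5 ± 0.997 CPM (log2 2.65 ± 0.12, edgeR adjusted p = 5.53e-06), and Gbp3, Gbp5 and Gbp6, guanylate-binding proteins, rose by 1.26 ± 0.08, 1.36 ± 0.12 and 1.40 ± 0.13. Of the MHC class I genes 14 rose and 1 was not called of 15 measured (14 higher when adjusted over the list alone). Their median was 0.45 (camera adjusted p = 2.60e-07, and adjusted p = 0.248 with an estimated correlation). The transactivator gene Nlrc5 lay at 1.22 ± 0.11, Tapbp at 0.65 ± 0.06, H2-Q6 at 0.71 ± 0.06 and H2-Q7, whose counts nearly equal those of H2-Q9, at 0.83 ± 0.05. Of the MHC class II genes 8 rose and 2 were not called of 10 measured (8 higher when adjusted over the list alone). Their median was 0.71 (camera adjusted p = 3.86e-04, and adjusted p = 0.288 with an estimated correlation). Their transactivator gene Ciita rose by 0.94 ± 0.09, Cd74, the invariant chain, went from 339 ± 12 to 627 ± 18.1 CPM, and H2-DMb1 and H2-Ab1 rose by 0.80 ± 0.08 and 0.75 ± 0.08. Of the complement genes 14 rose and 2 were not called of 16 measured (15 higher when adjusted over the list alone). Their median was 0.92 (camera adjusted p = 8.45e-09, and adjusted p = 0.178 with an estimated correlation). C3 went from 55.4 ± 7.27 to 265 ± 24.9 CPM and C1ra, C1qc and C1s lay at 1.20 ± 0.04, 1.06 ± 0.05 and 0.95 ± 0.05.

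Some markers of immune cells also rose in duodenum. Of the monocyte genes 7 rose and 1 fell of 8 measured (7 higher and 1 lower when adjusted over the list alone). Their median was 1.20 (camera adjusted p = 3.86e-04, and adjusted p = 0.248 with an estimated correlation). Ccr2, the chemokine receptor of inflammatory monocytes, went from 1.5 ± 0.123 to 10.3 ± 0.979 CPM, Chi3l3 from 0.152 ± 0.021 to 2.25 ± 0.253 CPM and Ms4a4c rose by 1.98 ± 0.21, while Plac8, which is abundant in this tissue, fell from 2557 ± 109.6 to 1735 ± 89.1 CPM. Of the dendritic cell genes 11 rose, 1 fell and 2 were not called of 14 measured (12 higher and 1 lower when adjusted over the list alone). Their median was 0.96 (camera adjusted p = 8.88e-05, and adjusted p = 0.229 with an estimated correlation). Itgax (CD11c), Zbtb46 and Fscn1 lay at 0.95 ± 0.06, 1.40 ± 0.18 and 1.00 ± 0.13 and Cd209a at -1.55 ± 0.24. Of the T cell genes 4 rose and 8 were not called of 12 measured (4 higher when adjusted over the list alone). Their median was 0.42 (camera adjusted p = 0.00702, and adjusted p = 0.248 with an estimated correlation). Cd4, Thy1 and Lck lay at 0.51 ± 0.09, 0.60 ± 0.11 and 0.58 ± 0.11. The neutrophil list held 9 genes measured in this tissue: 5 rose, 1 fell and 3 were not called of 9 measured (6 higher and 2 lower when adjusted over the list alone). Its median was 0.84 (camera adjusted p = 0.0577). Mmp9, Csf3r, Cxcr2 and S100a8 lay at 1.28 ± 0.11, 1.53 ± 0.15, 1.98 ± 0.35 and 1.38 ± 0.26. Of the red pulp macrophage markers 5 rose, 1 fell and 2 were not called of 8 measured (5 higher and 2 lower when adjusted over the list alone) (camera adjusted p = 0.0681). Axl lay at 0.92 ± 0.05, Csf1r at 0.68 ± 0.06 and Emr1, the F4/80 antigen, at 0.49 ± 0.08. Of the marginal zone macrophage markers 3 rose and 2 were not called of 5 measured (3 higher when adjusted over the list alone) (camera adjusted p = 0.0681). Timd4, Msr1 and Siglec1 lay at 1.21 ± 0.15, 1.20 ± 0.13 and 0.96 ± 0.12. Of the natural killer and cytotoxic genes 1 rose and 6 were not called of 7 measured (0 called when adjusted over the list alone) (camera adjusted p = 0.0575), the perforin gene Prf1 lying at 1.05 ± 0.31. Of the plasma cell genes 1 fell and 8 were not called of 9 measured (0 called when adjusted over the list alone) (camera adjusted p = 0.871). The list had a median of -0.02 and a mean of 0.02, with Sdc1 at -0.24 ± 0.07. The germinal centre call was S1pr2 at 1.19 ± 0.13: 1 rose and 6 were not called of 7 measured (1 higher when adjusted over the list alone) (camera adjusted p = 0.169).

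Many metabolic genes of the absorptive epithelium fell in duodenum. Of the cholesterol synthesis genes 16 fell and 1 was not called of 17 measured (16 lower when adjusted over the list alone). Their median was -0.77 (camera adjusted p = 9.06e-08, and adjusted p = 0.288 with an estimated correlation). Hmgcs1, the cytosolic HMG-CoA synthase, fell from 329.9 ± 76.1 to 152 ± 8.18 CPM, and Sqle, Lss and Dhcr7, later enzymes of the pathway, by 0.93, 0.93 and 0.60 on the log2 scale. Of the drug metabolism genes 1 rose, 13 fell and 2 were not called of 16 measured (1 higher and 14 lower when adjusted over the list alone). Their median was -0.53 (camera adjusted p = 7.48e-05, and adjusted p = 0.288 with an estimated correlation). Cyp2b10, Cyp3a25, Gstm3 and Sult1b1 lay at -0.94 ± 0.12, -0.83 ± 0.08, -0.67 ± 0.11 and -0.53 ± 0.05. Of the lipid absorption genes 3 rose, 10 fell and 3 were not called of 16 measured (3 higher and 11 lower when adjusted over the list alone). Their median was -0.37 (camera adjusted p = 0.00519, and adjusted p = 0.264 with an estimated correlation). Fabp1, Abcg8, Cd36 and Mogat2 lay at -0.61 ± 0.08, -0.57 ± 0.09, -0.53 ± 0.08 and -0.51 ± 0.06. Of the enterocyte genes 1 rose, 8 fell and 2 were not called of 11 measured (1 higher and 8 lower when adjusted over the list alone). Their median was -0.29 (camera adjusted p = 0.00393, and adjusted p = 0.248 with an estimated correlation). Sis, sucrase-isomaltase, fell from 3999 ± 212 to 2522 ± 337 CPM and the glucose transporter gene Slc5a1 from 3601 ± 33.1 to 2806 ± 221 CPM. Of the iron genes 3 fell and 7 were not called of 10 measured (3 lower when adjusted over the list alone) (camera adjusted p = 0.102). The iron exporter gene Slc40a1 lay at -0.52 ± 0.09, Tfrc at -0.50 ± 0.10 and Fth1 at -0.31 ± 0.07.

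The largest named falls in duodenum included Ccl28 and Il22ra1, genes of mucosal IgA and interleukin 22. Ccl28, a chemokine for IgA plasma cells (chromosome 13, 119623819 to 119654359, plus strand), fell from 42.9 ± 9.05 to 10.6 ± 0.31 CPM (log2 -2.03 ± 0.14, edgeR adjusted p = 4.02e-05). Outside the 8 largest named falls, Pigr, the receptor that carries IgA into the lumen, fell from 4620.4 ± 419 to 2139 ± 189.9 CPM. Il22ra1, the interleukin 22 receptor chain of epithelium (chromosome 4, 135728172 to 135752140, plus strand), fell from 144 ± 15.8 to 43.2 ± 7.83 CPM, while Il22ra2, its soluble decoy, rose by 1.46 ± 0.24. Of the interleukin 17 and 22 list 1 rose, 2 fell and 3 were not called of 6 measured (2 higher and 2 lower when adjusted over the list alone), with a median of 0.01, a mean of -0.14 and a downward test (camera adjusted p = 0.802). Of the IgA switch list 3 rose, 5 fell and 2 were not called of 10 measured (3 higher and 5 lower when adjusted over the list alone) (camera adjusted p = 0.177). Tgfb1 lay at 0.90 ± 0.07 and Aldh1a2 at -0.41 ± 0.06. The further falls were Rbp7, a retinoid-binding protein, at -1.88 ± 0.18, Ros1 at -1.84 ± 0.19, Apol10a at -1.82 ± 0.15, Dnase1 at -1.80 ± 0.13, the homeobox gene Barx2 at -1.56 ± 0.15 and Cd209a, from 3.85 ± 0.765 to 1.31 ± 0.349 CPM.

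Antimicrobial and secretory genes went both ways in duodenum. Of the antimicrobial and acute phase list 7 rose, 5 fell and 5 were not called of 17 measured (7 higher and 6 lower when adjusted over the list alone). Its median was 0.22 (camera adjusted p = 0.839). The lectin gene Reg3g went from 119 ± 52.8 to 866 ± 306 CPM and Nos2 from 1.57 ± 0.698 to 6.96 ± 0.93 CPM, while Retnlb, a goblet cell product with 57 counts over the isotype and 5 over the AC H6 libraries, fell by 3.79 on the log2 scale. Of the goblet cell genes 1 rose, 3 fell and 5 were not called of 9 measured (1 higher and 4 lower when adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.349). Clca3 lay at -0.41 ± 0.08 and Zg16 at -0.39 ± 0.11. The rise in that list was Ccl9, which the M cell list also holds. Of the Paneth cell genes 1 rose, 5 fell and 10 were not called of 16 measured (1 higher and 7 lower when adjusted over the list alone). Their median was -0.31 (camera adjusted p = 0.019, and adjusted p = 0.625 with an estimated correlation). The angiogenin gene Ang4 lay at -0.73 ± 0.15, the defensin genes Defa26 at -0.51 ± 0.11 and Defa23, whose counts nearly equal those of Defa-rs7, at -0.54 ± 0.11, and the protease gene Mmp7 at 0.97 ± 0.20. The Paneth call had an adjusted p of 0.104 without isotype 2, 0.0607 without AC H6 1 and 0.0511 without AC H6 2.

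Many stem cell, proliferation, endocrine and stromal genes rose in duodenum. Of the stem cell genes 7 rose, 1 fell and 2 were not called of 10 measured (7 higher and 1 lower when adjusted over the list alone). Their median was 0.49 (camera adjusted p = 0.019, and adjusted p = 0.277 with an estimated correlation). Ascl2 lay at 1.31 ± 0.14, Tnfrsf19 at 0.66 ± 0.11, Smoc2 at 0.58 ± 0.06 and Rnf43 at -0.55 ± 0.08. Of the cell cycle genes 15 rose and 5 were not called of 20 measured (16 higher when adjusted over the list alone). Their median was 0.44 (camera adjusted p = 3.59e-06, and adjusted p = 0.277 with an estimated correlation). Mcm3, Mcm5, Aurkb and Tyms lay at 0.68 ± 0.10, 0.65 ± 0.07, 0.54 ± 0.07 and 0.45 ± 0.06. Of the enteroendocrine genes 6 rose and 6 were not called of 12 measured (7 higher when adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.00225, and adjusted p = 0.251 with an estimated correlation). Chgb lay at 0.47 ± 0.06, Chga at 0.41 ± 0.07 and Pyy at 0.54 ± 0.10. Of the stroma list 7 rose and 5 were not called of 12 measured (7 higher when adjusted over the list alone). Its median was 0.43 (camera adjusted p = 0.0184, and adjusted p = 0.277 with an estimated correlation). Dcn, Col1a2 and Col1a1 lay at 0.77 ± 0.09, 0.66 ± 0.07 and 0.65 ± 0.09. The stroma call had an adjusted p of 0.0672 without AC H6 1. Of the brain list 4 rose and 4 were not called of 8 measured (4 higher when adjusted over the list alone). Its median was 0.29 (camera adjusted p = 0.0193, and adjusted p = 0.248 with an estimated correlation). Camk2a, Gfap, Aqp4 and Mbp lay at 0.77 ± 0.14, 0.86 ± 0.20, 0.47 ± 0.15 and 0.28 ± 0.06, genes that neurons and glia of the gut wall also express in part. Of the endothelium genes 4 rose, 1 fell and 5 were not called of 10 measured (5 higher and 2 lower when adjusted over the list alone) (camera adjusted p = 0.297). Pecam1 lay at 0.64 ± 0.08 and Emcn at -0.42 ± 0.09. Of the tuft cell genes 4 rose and 4 were not called of 8 measured (4 higher when adjusted over the list alone) (camera adjusted p = 0.134). The tuft cell transcription factor gene Pou2f3 lay at 0.53 ± 0.16. Of the erythroid genes 2 rose, 1 fell and 11 were not called of 14 measured (1 lower when adjusted over the list alone) (camera adjusted p = 0.813). Of the platelet genes 1 rose and 4 were not called of 5 measured (1 higher when adjusted over the list alone) (camera adjusted p = 0.965). Pf4 lay at 1.00 ± 0.14, the median at -0.17, the mean at 0.09 and the test pointed down. Of the clock genes 1 rose, 3 fell and 12 were not called of 16 measured (1 higher and 2 lower when adjusted over the list alone) (camera adjusted p = 0.0945). Npas2 lay at 0.67 ± 0.10 and Cry2 at -0.68 ± 0.11. Of the immediate early and stress genes 1 rose, 2 fell and 13 were not called of 16 measured (0 called when adjusted over the list alone) (camera adjusted p = 0.714). The chaperone gene Hsph1 lay at 1.01 ± 0.25 and Fosb, with overlap between the groups, at -1.10 ± 0.33.

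Of 15667 genes tested in duodenum, edgeR called 2899 higher and 2529 lower, 5428 in all or 34.6%. Of these 488 and 78 changed by more than 1 on the log2 scale. In 5376 of the 5428 every AC H6 library lay above or below every isotype library, as in 7742 of all genes, where chance alone gives 10%. The camera test called 23 of 41 lists, 18 up and 5 down, and 0 with an estimated correlation, with 5 lists at an unadjusted p under 0.05. Of the 153 called genes that the naming rule picked, 136 stayed past the threshold whichever library was left out.

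**Figure D2:**
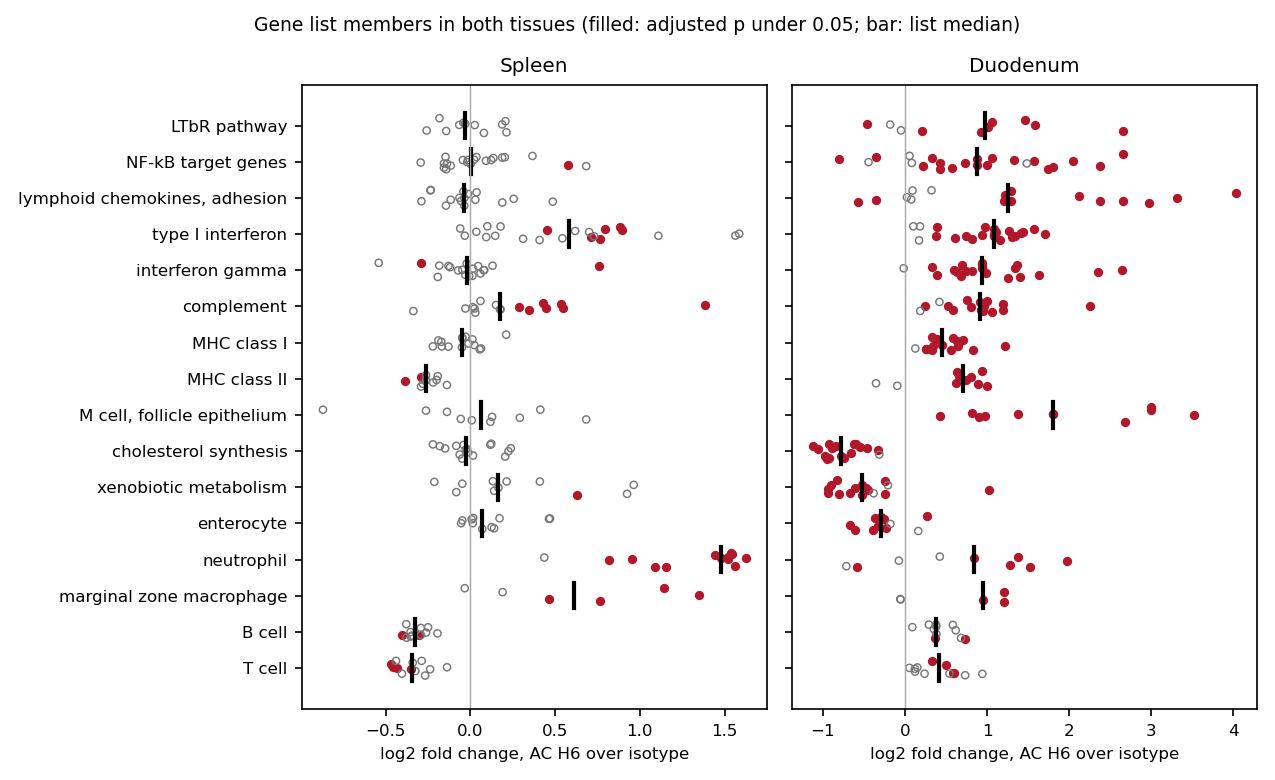
Log2 fold change of AC H6 over isotype (horizontal axis) for each measured member of 16 of the gene lists (vertical axis), in spleen and in duodenum, with 1 point per gene, filled where the adjusted p was under 0.05, and a bar at the list median. Of the lists drawn, the neutrophil list lies highest in spleen with a median of 1.48, and the M cell list has a median of 1.80 in duodenum.

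The interaction comparison asked whether the response differed between the tissues, through the product term of tissue and treatment in 1 fit of all 12 libraries. By adjusted p, the 10 genes that differed most surely were these: the duodenum response exceeded that of spleen by 2.92 ± 0.08 on the log2 scale for Mfge8 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.57e-09), by 2.45 ± 0.11 for Nfkb2, 1.83 ± 0.10 for Map3k14, 2.37 ± 0.09 for Icam1 and 3.76 ± 0.15 for Spib. Marcksl1, Il4i1, Colq and Lpcat4, an enzyme of phospholipid remodelling (chromosome 2, 112239468 to 112247111, plus strand), differed by 2.65 ± 0.09, 3.93 ± 0.14, 3.62 ± 0.18 and 2.13 ± 0.09. Ubd differed by 7.10 ± 0.27. Ubd, Il4i1 and Colq were called in opposite directions in the tissues, with log2 changes of -1.03, -0.42 and -0.66 in spleen. Beyond the 10 genes of smallest adjusted p, Cxcl13 differed by 4.13 ± 0.22, Madcam1 by 2.39 ± 0.16, Relb by 1.18 ± 0.13, Ccl19 by 3.26 ± 0.18, C3 by 1.81 ± 0.14 and Cxcl10 by 1.87 ± 0.15. Hp, S100a8 and Cd209a, called in both tissues in the same direction, had differences of -0.04, -0.16 and -0.55 (edgeR adjusted p = 0.991, 0.835 and 0.2). These 9 genes were chosen after their values were seen. Of 16655 genes tested, 3331 were called, with the duodenum response higher in 1810 and lower in 1521. Of these genes 2469 had been called in duodenum alone, 154 in spleen alone, 46 in both in the same direction, 78 in both in opposite directions and 584 in neither. Without spleen isotype 1 the count of lower responses was 943.

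The last comparison counted genes called in both tissues among the 14366 tested in both. There were 128 genes higher in both, against 53.3 for independent lists of these sizes, among them Hp, S100a8, S100a9, Csf3r, Mmp9, Chi3l3, F13a1, Oas1a, Oas2, Cxcl10, Nos2 and C5ar1. There were 53 lower in both against 44.5, Cd209a and Cry2 among them. In opposite directions, 28 lay higher in spleen and lower in duodenum against 44.8. Of these, 8 were Ugt1a genes with nearly the same log2 changes, Ugt1a1 among them, so they repeat 1 signal. Another 50 were lower in spleen and higher in duodenum against 52.9, with Stra6, Ubd, Cxcl9, Cd3e and Ccr7 among them. Together 181 genes moved in the same direction. That count was 7, 30 and 44 without spleen isotype 1, 2 and 3, and 36, 283 and 17 without spleen AC H6 1, 2 and 3.

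**Figure D3:**
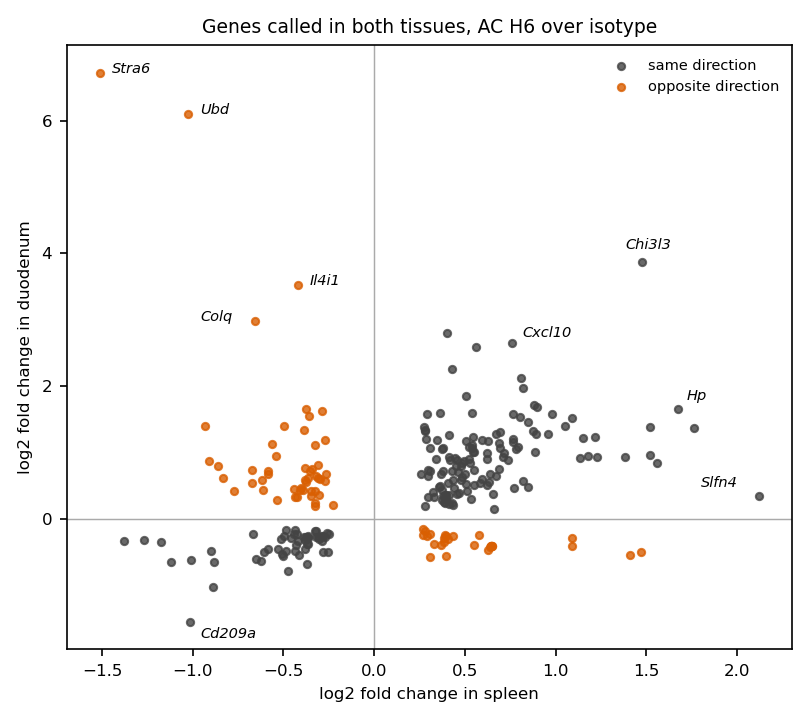
Log2 fold change of AC H6 over isotype in spleen (horizontal axis) against that in duodenum (vertical axis), 1 point per gene called in both tissues, grey where the direction was the same and orange where it was opposite. The 181 points of the same direction lie in the upper right and lower left, and Stra6 and Ubd stand at the top of the upper left.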

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

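Among the tests in this part, those of lymphoid follicles, a lower share of lymphocytes and erythroid content as the whole cause were chosen only after the result was seen, as were the fits with an erythroid or acinar score and without abundant genes.

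The test of the difference between tissues singled out 3331 genes. The 10 smallest adjusted p were those of Mfge8 (2.92 on the log2 scale), Marcksl1 (2.65), Il4i1 (3.93), Icam1 (2.37), Ubd (7.10), Spib (3.76), Lpcat4 (2.13), Nfkb2 (2.45), Colq (3.62) and Map3k14 (1.83). Further named genes were called in opposite directions in the tissues and were kept here only if that test called them. Stra6 differed by 8.22, which depends on the prior count since 3 counts lie behind its isotype value in duodenum. Cxcl9 differed by 1.90, Cd3e by 0.74, Ccr7 by 1.05 and Ugt1a1 by -1.12. For the whole count, 1 of 100 splits of the libraries gave as many genes, the real one with 3331, and the highest other gave 2300. Splits that mix the duodenum groups put the response of that tissue into the residual spread. Only the real split and 7 others, with 1477 to 2300 genes, kept these groups whole, too few for a share under 0.05.

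A first pattern is the rise of 11 of 11 M cell genes in duodenum with a median of 1.80. Pieces with more lymphoid follicles would bring B cells, and the B cell genes had a median of 0.38 (SD 0.191, n = 11 genes), 2 of them called. That rise was smaller than the rise of the M cell genes. Its size depends on how many B cells the isotype pieces already held, so follicles taken with the AC H6 pieces stay open. Without isotype 1, the library rich in Rn45s, 10 of the 11 were still called, and with the acinar score as a covariate 11 were, which argues against ribosomal RNA or pancreas as the whole cause, although Gp2 was highest in the libraries richest in amylase 2. A response of the epithelium to the antibody stays open as a hypothesis, and no test here bears on it directly.

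A second pattern is the rise of 12 of 13 neutrophil genes in spleen, with a median of 1.48. A lower share of lymphocytes would raise stroma, endothelium and red pulp macrophage genes alike, but their median was -0.0520 (standard error 0.0639, n = 32 genes) where 0.74 (0.5 of the neutrophil median) would have been needed. The erythroid score as a covariate lowered the neutrophil median to 1.01 and left 12 of 13 genes called, which argues against erythroid content as the whole cause and leaves a part open. Leaving out haemoglobin and other abundant genes gave 1.48 but moved genes by a median of only 1.70e-04, so it decides nothing. More neutrophils in spleen, or more of these transcripts per cell, may both stand behind the pattern, and whole-tissue RNA cannot separate them.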

How the results depend on the processing

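The fits with an erythroid score, with an acinar score and without abundant genes were chosen only after the data were seen. No named gene or list that was called in the main fit or the alternative reversed its direction. No count of genes in duodenum moved by over 1.5 times. Higher calls outnumbered lower ones in the main fits and most alternatives. Lower ones led in duodenum with DESeq2 (2526 higher, 2587 lower) and in 1 fit of 12 libraries (2603 and 2694). They led in spleen with limma-voom (288 and 298) and the stricter filter (313 and 335), and in the interaction with DESeq2 (1727 and 1746). In spleen the 608 calls (315 higher, 293 lower) became 1356 with DESeq2 (816 and 540), 1390 in 1 fit of 12 libraries (781 and 609) and 207 with the erythroid score (134 and 73). Leaving out single libraries gave 14 to 1132 calls, 12 to 575 higher and 2 to 557 lower, and the cause was not tested beyond the loss of 1 of 6 libraries. The interaction genes with a lower response in duodenum, 1521, ran from 943 to 1763. Genes called in both tissues in the same direction, 181, became 395 with DESeq2 and 387 in 1 fit, and 7 to 283 without single libraries. The camera calls, 13 lists in spleen and 23 in duodenum, became 0 and 0 with an estimated correlation, where 4 and 5 lists had an unadjusted p under 0.05. With the replicate number as a block, spleen had 1 call (1 higher, 0 lower by edgeR, with 2016 and 1650 at an unadjusted p under 0.05), duodenum 5421 and the interaction 3082. The same-numbered libraries of spleen had correlations of 0.26, -0.13 and -0.03 and those of duodenum 0.40, 0.24 and -0.20. So few values neither show nor exclude that the numbers pair libraries within a tissue.

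Setting aside the block and single libraries, 36 of the 71 called named genes of spleen and 138 of 153 of duodenum kept their calls under every alternative that tested them. Genes that a filter removed were not tested there. In the spleen, 1 of 10 splits of the libraries gave as many genes as the real one (608, highest other 0, with 1349 genes at an unadjusted p under 0.05 against 4260 in the real one) and 3 of 10 as many lists (13, highest other 14), and in duodenum 1 of 10 did for genes (5428, highest other 0, with 422 against 7112) and 1 of 10 for lists (23, highest other 15). With only 10 splits, these counts are too few for a share under 0.05. For the 181 genes of both tissues 1 of 200 splits that relabel each tissue by itself gave as many, and the highest other gave 78, the real labels with those of 1 tissue swapped. The outcome of the rest is fixed by the splits of each tissue, so these are too few as well. Same-numbered spleen and duodenum libraries had correlations of 0.21, 0.38 and 0.12 in isotype and 0.14, 0.17 and -0.18 in AC H6, which leaves open whether they share a mouse.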

Other observations

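The tests of skeletal muscle and peripheral nerve, and the choice of the gene families below, came only after the values were seen.

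Gene families, some with members in the fixed lists, also moved in duodenum. All 3 measured Gsdmc genes of the gasdermin family fell, Gsdmc2, Gsdmc3 and Gsdmc4 from 128, 73 and 248 counts over the isotype libraries to 11, 6 and 6 over the AC H6 libraries, log2 changes of -3.83 ± 0.59, -3.86 ± 0.59 and -5.62 ± 0.47. Some genes rose from near 0: Xlr5a had 1 against 240 counts, a ratio of 184 (95% counting interval 32.7 to 7285), Xlr5b and Xlr5c had 0 against 289 and 171, at least 73.7-fold and 43.6-fold higher with the floor of 3 counts over the group, and Khdc1c 3 against 88, a ratio of 22.4 (7.43 to 111). Psg22 rose by 4.79 ± 0.40 and Khdc1a by 4.27 ± 0.45. These genes belong to families of close copies, so the copy a read came from is uncertain. All 5 measured Serpina3 genes rose, by 1.68 to 2.58, as did 10 of 11 Gbp genes, 8 of 9 Oas genes and 3 of 4 Reg3 genes. Of the tumour necrosis factor ligand genes 4 rose, among them Tnfsf11 (RANKL) by 2.66 ± 0.32 and Tnfsf15 by 2.15 ± 0.19, and 2 fell, with Tnfsf13b (BAFF) at -0.57 ± 0.11.

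In spleen, 8 of 8 granule genes of neutrophil and basophil precursors rose, Elane by 1.52 ± 0.25, Ctsg by 1.44 ± 0.27, Camp by 1.44 ± 0.26 and Mcpt8 by 1.51 ± 0.27. These 8 were picked by hand after their values were seen and include Mpo and Prtn3, so their count is no separate support. Of the stromal genes looked up, Des and Nr5a1, a transcription factor of spleen stroma, rose by 0.58 ± 0.06 and 0.61 ± 0.06, while Mgp, Mmp2 and Wnt11 changed by -1.01 ± 0.13, -0.72 ± 0.11 and -0.91 ± 0.18. Of the Gbp genes, where 10 of 11 rose in duodenum, 1 of 11 passed in spleen, Gbp4 at -0.31 ± 0.06.

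Another pattern is a fall of some muscle and nerve genes in spleen: Myh8 went from 3.04 to 0.441 CPM (log2 -2.74 ± 0.26), Snap91 and Nell2 changed by -2.44 and -2.12, and Myh2, Tnnt3 and Myh1 by -1.51, -1.02 and -0.94. If skeletal muscle had come with the isotype spleens, its abundant genes would have fallen with Myh8. The 11 muscle genes looked up had a median of -0.309 (standard error 0.195) against -1.37 needed. Acta1, the abundant actin of skeletal muscle, held 0.978 CPM in isotype and 0.921 with AC H6, while Myh8 lost 2.60 CPM. Mylpf (6.48 and 6.60 CPM) and Tnni2 (3.51 and 3.53 CPM) did not fall either. These values argue against skeletal muscle as the source of the Myh8 fall. Myh1, Myh2 and Tnnt3 among the 11 were called lower, but they are part of the pattern itself, and their falls stay open. For nerve, 9 of 10 glial genes looked up had a median of 0.00758 (standard error 0.191), but a small amount could hide below the spread of the abundant markers, so a trace of nerve stays open. No biological explanation was tested.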
